A study of Homo sapiens with 3 samples.

How the data were processed

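Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in HT1080 cells, an established human fibrosarcoma line, with antibodies against XPB and XPD, the 2 helicase subunits of the general transcription and DNA repair factor TFIIH. The series holds 3 samples: 1 XPB ChIP, 1 XPD ChIP and 1 input DNA library that was not enriched. Per the labels' protocols, fragments of 400 to 700 bp were selected, and the ChIP libraries were amplified for 12 cycles and the input for 9. All came from a single pool of crosslinked chromatin, per the series' design text. The groups were taken from the sample titles and the antibody fields. The protocol text that the samples share names an antibody against a different protein (CSB), while each sample's own antibody field names XPB or XPD; the antibody fields were followed.

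Reads were aligned to the hg19 build with Bowtie 0.12.7 and peaks were called with MACS 1.4, per the submitters' processing notes. A list was deposited for each ChIP sample separately, with no pooling. The labels do not state that the input served as the control, nor any other caller setting, and no peak list of the input was used here. Each list has a file of peak intervals with a score and a file of summits with a height. The column meanings were taken from the usual MACS layout: the deposited peak score is -10 times the log10 of the caller's p-value, and the deposited summit signal is the height of the fragment pileup at the summit, a whole number not scaled to library depth. The lowest score in either file was 150 and the highest 3100, which the values show to be a ceiling. Peak names carry a rank by score, and the ranks ran without a gap in both lists. The number of reads per library is unknown from these files, so heights and scores were not compared between antibodies as absolute levels.

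Positions are given as 1-based hg19 coordinates. No hg19 sequence or annotation was used here, and the gene table at hand is of another assembly, so peaks were not assigned to genes. The planned comparisons of peaks with transcription start sites, with G-quadruplex motifs and with fixed gene lists were therefore not run.

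Peaks were called shared when their intervals overlapped by at least 1 bp. For each list, the percentage that overlapped the other list was set beside 1000 random placements of the other list, with peak widths kept and each peak placed anywhere between the first and last peak of its chromosome. A stricter reference moved each peak of the other list by a random 5 to 50 kb in either direction, which keeps the regional density. Pairs for height and summit comparisons were peaks that were each other's largest overlap. Percentages carry exact (Clopper-Pearson) 95% intervals, which cover counting error only, since peaks of 1 library are not replicates and PCR copies are not independent molecules. With 1 library per antibody no test between antibodies was possible, and no p-value is given. Correlations are across peaks or windows within these libraries. Intervals on correlations and on ratios of heights come from 1000 bootstrap draws over peaks.

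The named peaks followed a rule fixed before the data were examined: the 10 tallest summits of each list and the 5 tallest summits of each list with no overlapping peak in the other. The parts of the rule that needed gene annotation could not be applied. No peak lay on the mitochondrial genome or an unplaced contig. The overlap and placement functions were tested on simulated lists with the real widths and chromosomes: for 14570 simulated XPD peaks with 0, 30 or 60% planted on XPB peaks, 1.91, 31.2 and 60.8% were recovered, where random placement alone gave 1.75 to 1.82%. Alternatives for the overlap rule, score threshold, list length, placement and correlation measure were also run. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.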

Results

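The data comprised 2 peak lists, from a ChIP of XPB and a ChIP of XPD in HT1080 cells, with 1 library for each protein. XPB and XPD are the helicases of TFIIH, which opens promoter DNA for RNA polymerase II and the damaged strand in nucleotide excision repair. The series asked where in the genome each helicase was bound. The XPB list held 21555 peaks that covered 19.2 Mb, and the XPD list held 14570 peaks that covered 14.5 Mb, a ratio of 1.48 in number. XPB peaks had a median width of 833 bp (interquartile range 651 to 1052) and XPD peaks of 937 bp (730 to 1181). The median summit height was 11 fragments in the XPB list (9 to 14) and 13 in the XPD list (11 to 15). Most summits were therefore low, and only 74 XPB and 81 XPD summits reached 50 fragments. The median score was 189.4 for XPB and 185.1 for XPD, against a lowest listed score of 150. The sequencing depth of the libraries is unknown from the lists, so the difference in peak number was not read as a difference in binding.

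The first comparison was whether the helicases occupied the same sites. The strongest sites were common to both, and most of the weaker ones appeared in a single list. Of the XPB peaks, 5727 (26.6%, 95% interval 26.0 to 27.2) overlapped an XPD peak. Of the XPD peaks, 5639 (38.7%, 37.9 to 39.5) overlapped an XPB peak. Random placement on the same chromosomes gave 1.21% ± 0.0766 (SD over 1000 placements, highest 1.46) for XPB and 1.78% ± 0.110 (highest 2.19) for XPD, so the observed overlap was 21.9 and 21.7 times that level. Moving the other list's peaks by 5 to 50 kb, which keeps them in the same neighbourhoods, gave 4.14% ± 0.132 (highest 4.56) for XPB and 6.02% ± 0.187 (highest 6.62) for XPD, and the overlap was then 6.42 and 6.43 times the local level. Both ChIPs came from the same chromatin pool, and features of that chromatin or of a common control are not modelled by random placement.

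The overlap followed the peak score. In the highest decile of XPB scores (345.1 and above), 80.6% of peaks (78.8 to 82.2) overlapped an XPD peak, compared with 48.5% in the second decile and 9.65% (8.44 to 10.98) in the lowest. In the XPD list the highest decile (319.4 and above) reached 90.3% (88.6 to 91.7), the second 61.9% and the lowest 19.97% (17.9 to 22.1). All 216 XPB peaks and all 146 XPD peaks in the top 1% by score had an overlapping partner. Even the lowest deciles lay above the mean of the local placements for the whole list. Height gave the same order: 15.2% of XPB peaks with summits of 6 to 9 fragments were shared, and 93.4% (89.7 to 96.1) of those with 31 or more.

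**Figure D1:**
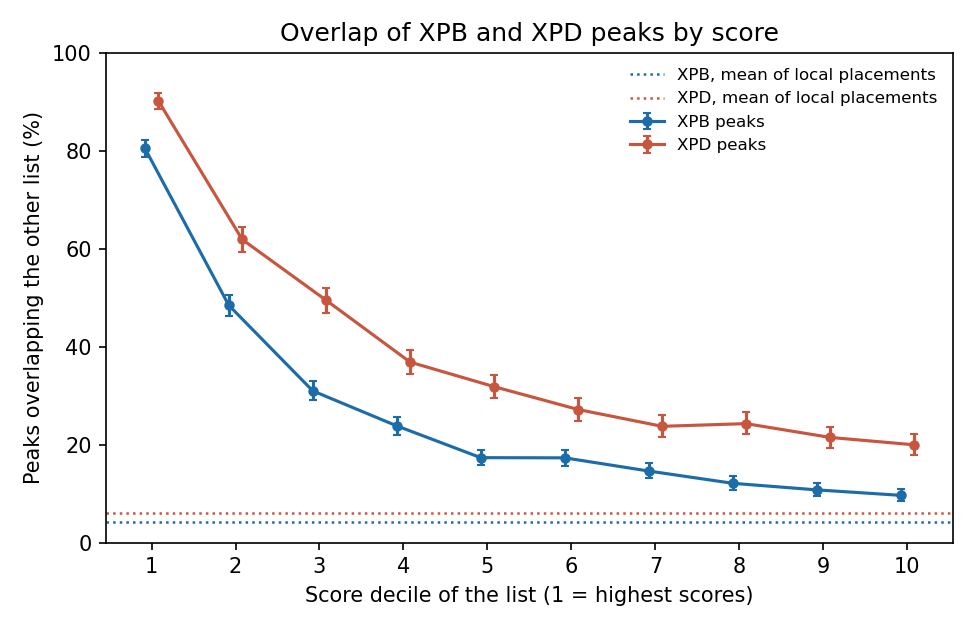
Percentage of peaks that overlap the other list (y axis) in each decile of peak score (x axis, 1 is the highest), for XPB (blue) and XPD (red); bars are exact 95% intervals and dotted lines the mean of local placements. The share falls from 80.6 to 9.65% for XPB and from 90.3 to 19.97% for XPD, and stays above the dotted lines.

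Shared peaks had higher scores than peaks of a single list. Shared XPB peaks had a median score of 259.2, and the 15828 XPB peaks with no XPD partner had 179.7. Shared XPD peaks had a median score of 221.2, and the 8931 XPD peaks with no XPB partner had 174.5. The ratio of median scores was 1.44 (1.41 to 1.46) for XPB and 1.27 (1.25 to 1.28) for XPD. Widths cannot be compared as plainly, because a wider peak meets the overlap rule more often: the ratio of median widths, shared over single-list, was 1.201 for XPB and 1.16 for XPD, against 1.08 ± 0.0264 and 1.08 ± 0.0284 (SD over random placements), and 1.11 and 1.045 when shared meant summits within 250 bp, a comparison chosen after the data were seen. A minority of single-list peaks nevertheless scored high: 826 XPB peaks and 223 XPD peaks without a partner scored 300 or more. The highest-scoring of these was an XPB peak on chromosome 14 from 89017530 to 89018460, with a summit of 37 fragments and a score of 764.5. On the XPD side it was a peak on chromosome 17 from 48738423 to 48739960, with a summit of 17 fragments and a score of 573.0. A high score did not always go with a tall summit: the XPB peak on chromosome 7 from 62404 to 66361 scored 702.9 with 11 fragments over 3958 bp. The single-list peaks named here were picked after their values were seen.

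At shared sites the summits of the helicases lay closer together than chance overlap gave. Among 5536 pairs of mutually best overlapping peaks, the summits lay a median of 97.5 bp apart (interquartile range 26 to 324), 50.7% (49.3 to 52.0) were within 100 bp and 68.5% within 250 bp. Peaks that happened to overlap in random placements had a median summit distance of 470 bp, 10.2% were within 100 bp and 26.5% within 250 bp. In the 1040 pairs with both scores at 300 or more the median distance was 49 bp and 63.5% (60.5 to 66.4) were within 100 bp. Libraries were cut to fragments of 400 to 700 bp, which limits how finely such distances can be read.

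Heights at shared sites were correlated. Across the 5536 pairs, Spearman's rho between XPB and XPD summit heights was 0.59 (bootstrap interval 0.58 to 0.61), and Pearson's r of the log2 heights was 0.76. Within single chromosomes rho ranged from 0.47 to 0.69 over the 22 autosomes. These values are across peaks, which are not independent replicates, and low summits in both lists are cut off by the score threshold. The median log2 ratio of XPD to XPB height was 0.11 (interquartile range -0.19 to 0.38), without adjustment for depth.

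**Figure D2:**
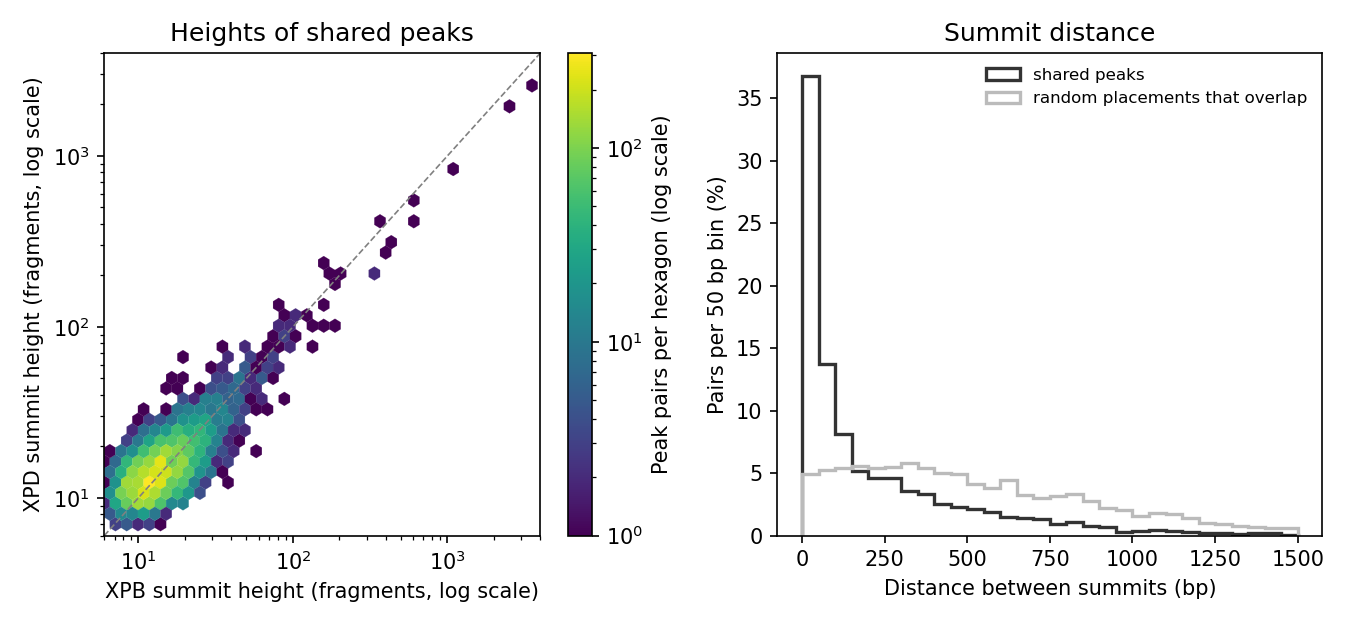
Left, XPB against XPD summit height (fragments, log axes) for 5536 shared pairs, coloured by the number of pairs per hexagon, with the line of equal height dashed. Right, distance between the XPB and XPD summits (bp) as a percentage of pairs per bin, for shared peaks (dark) and for random placements that overlap (grey); 50.7% of shared pairs lie within 100 bp against 10.2% of random ones, and the longest distances fall outside the axis.

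The tallest summits were almost the same sites in both lists. All 10 of the tallest XPB summits overlapped an XPD peak, all 10 of the tallest XPD summits overlapped an XPB peak, and 8 sites were in both sets. The tallest was on chromosome 1 from 91852662 to 91853220, with 3531 fragments for XPB and 2583 for XPD, followed by chromosome 21 from 9825441 to 9827797 (2728 and 2050) and chromosome 8 from 70602181 to 70602708 (1094 and 775). The first of these ranked only 836 by score in the XPB list and 2468 in the XPD list. Tall summits with scores at the ceiling of 3100 in both lists lay on chromosome 1 from 28974334 to 28975875 (635 for XPB and 540 for XPD), on chromosome 1 from 149222589 to 149224856 (561 and 418), on chromosome 17 from 41438036 to 41439127 (417 and 317) and on chromosome 2 from 122288036 to 122289205 (352 and 386). A narrow site on chromosome 5 from 71146718 to 71147002 had 405 and 283 fragments. The summits at these 8 sites were at most 10 bp apart between the lists. The remaining XPB sites were on chromosome X from 108297366 to 108297855 (316 for XPB and 197 for XPD) and chromosome 22 from 43010855 to 43012035 (313 and 200). The remaining XPD sites were on chromosome 11 from 62608246 to 62610099 (222 for XPD and 153 for XPB) and chromosome 2 from 121832355 to 121833372 (215 and 190). In all, 11 XPB and 8 XPD peaks sat at the score ceiling; 8 of the XPB ones overlapped XPD peaks at the ceiling, and the other 3 overlapped XPD peaks below it. No annotation of this build was used, so the genes or repeats at these positions are not named. The input was not compared at these sites, so a background common to both libraries is not separated from binding there.

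The tallest summits found in a single list were much lower, with 1 exception. An XPB peak on chromosome 12 from 20704266 to 20704913 had a summit of 259 fragments and no XPD peak over it. Its score was 431.6, which ranked only 1116 in the XPB list. The next XPB-only summits were on chromosome 4 from 49315982 to 49316501 (51 fragments), chromosome 15 from 41694382 to 41695087 (46), chromosome 14 from 89017530 to 89018460 (37) and chromosome 17 from 18965258 to 18965701 (37). The XPD-only summits were on chromosome Y from 58838513 to 58838787 (51 fragments), chromosome 3 from 112359850 to 112360520 (46), chromosome 4 from 67587 to 68459 (40), chromosome 5 from 21479140 to 21479700 (40) and chromosome 21 from 11118973 to 11119757 (40). With 1 library each, none of these has a replicate check.

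The last comparison was how the peaks were spread over the genome. The lists followed each other closely: across 3007 windows of 1 Mb, Spearman's rho between the XPB and XPD peak numbers was 0.89. Of these windows, 594 held no peak of either list, and such ties can raise rho. The ratio of XPB to XPD peaks per autosome stayed between 1.37 and 1.70. The mean density over the covered span was 7.22 XPB peaks and 4.88 XPD peaks per Mb. The densest autosome was chromosome 22, with 19.6 XPB and 13.1 XPD peaks per Mb, and the sparsest was chromosome 4, with 2.72 and 1.74. Chromosome 3 held the most peaks of any chromosome, 2420 for XPB and 1696 for XPD. Chromosome X held 47 XPB and 22 XPD peaks, 0.326 and 0.152 per Mb, and the autosomal mean was 23.7 and 34.3 times as high. Over the autosomes the overlap of the lists varied less: from 18.3% on chromosome 13 to 35.7% on chromosome 21 for XPB peaks, and from 29.7% on chromosome 4 to 45.6% on chromosome 21 for XPD peaks. On chromosome X it was 27.7% (15.6 to 42.6) of the XPB peaks and 59.1% (36.4 to 79.3) of the XPD peaks, and chromosome Y, with 4 XPB and 5 XPD peaks, held too few for a share. Within each list the peaks were clustered. A second peak of the same list lay within 10 kb of 41.8% of XPB summits (41.2 to 42.5) and 34.5% of XPD summits (33.8 to 35.3), against 16.7% ± 0.361 and 11.9% ± 0.331 (SD over random placements).

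**Figure D3:**
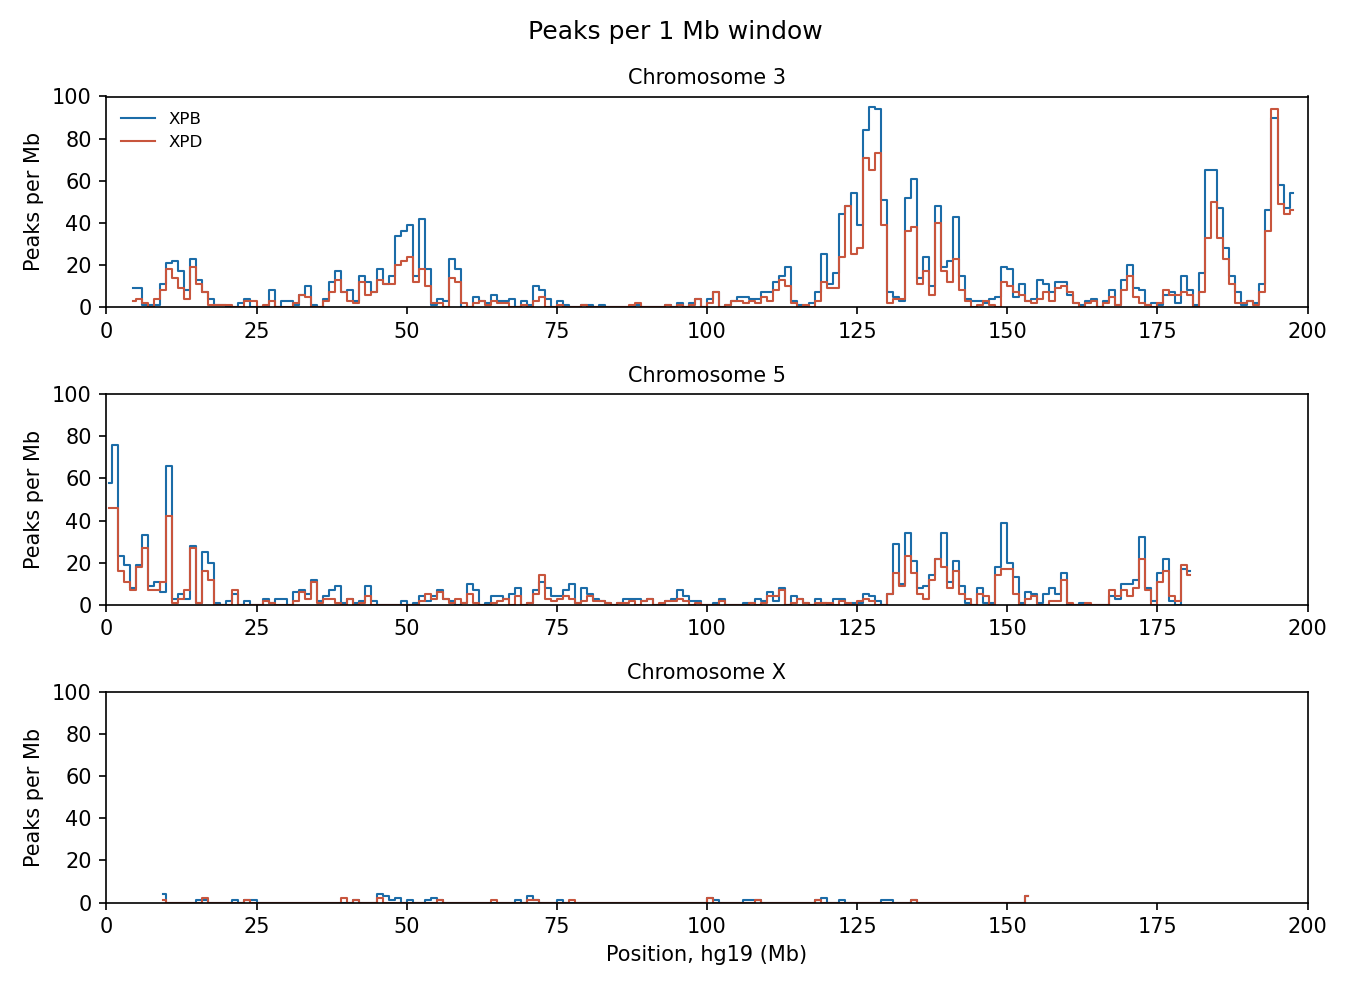
Number of XPB (blue) and XPD (red) peaks in each 1 Mb window (y axis) along chromosomes 3, 5 and X (x axis, hg19 position in Mb, all panels to the same scale). Chromosome 3 has windows with up to 95 XPB and 94 XPD peaks, chromosome 5 has its densest windows near its start, and chromosome X holds 47 XPB and 22 XPD peaks in all.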

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

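Of 34 alternatives, 9 stayed within the counting or bootstrap interval of the reported value and 25 moved outside it. The higher share in the XPD list did not hold with the lists cut to the same number of peaks, and that most peaks lack a partner did not hold in every setting with scores of at least 300. The share of XPB and of XPD peaks that overlapped the other list was 21.7 and 32.2% with a reciprocal overlap of 50%, 17.9 and 26.4% with summits within 250 bp, and 34.0 and 33.8% with the lists cut to the same number of peaks. A score of at least 100 removed no peak and is uninformative, although its settings are counted among the 9 that stayed. Thresholds added after seeing the data gave 30.5 and 49.1% at scores of at least 200 in both lists, 35.3 and 61.8% at scores of at least 300 in both lists, and 73.2 and 87.1% for peaks scoring at least 300 against the whole other list. The fold over random placements (21.9 and 21.7) was 6.42 and 6.43 with placement within 5 to 50 kb, 56.2 and 56.5 with summits within 250 bp, and 22.9 and 22.7 without chromosome 3. The correlation of summit heights (rho 0.59) was 0.76 as Pearson's r of log2 heights, 0.54 without the tallest 1% of either list, 0.64 at scores of at least 200, and 0.46 with score in place of height. The ratio of median XPB scores between shared and single-list peaks was 1.49 with summits within 250 bp. Leaving out chromosome 3, or peaks in the top 1% of height over score, kept both overlap shares within their intervals. The settings for transcription start sites, G-quadruplex motifs and gene lists were not run, for want of hg19 sequence and annotation. Unknown read depth and the floor at a score of 150 limit how far absence from a list can be read as absence of binding.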

Other observations

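The windows below, the height ratios and the test of summits of 50 fragments or more were chosen after the data were seen; the tests of score, near-threshold height and chromosome X density were fixed before their results were computed. Windows dense in XPB peaks were often dense in XPD peaks too. Of 3007 windows of 1 Mb, 74 held at least 5 times the mean number of XPB peaks and 73 at least 5 times the mean of XPD peaks; 51 did both, where independent lists would share 1.80. These 51 lay on 13 chromosomes, and chromosome 3 had 18 of them, ahead of 6 on chromosome 1 and 5 on chromosome 19. A run on chromosome 3 of 7 adjoining windows from 123000001 to 130000000 held 39 to 95 XPB peaks and 25 to 73 XPD peaks each, and another of 5 from 193000001 to 198000000 held 46 to 90 and 36 to 94. In the latter, the window from 194000001 to 195000000 held 90 XPB and 94 XPD peaks, the most XPD peaks of any window. The 18 windows took up 0.603% of the span and held 5.09% of XPB and 5.82% of XPD peaks. The rest of chromosome 3 had 7.53 XPB and 4.83 XPD peaks per Mb. The means, with all dense windows kept in, were 7.22 and 4.88 over all chromosomes and 7.73 and 5.23 over the autosomes. On chromosome 5, the first 2 windows held 58 and 76 XPB peaks and 46 XPD peaks each, and the window from 10000001 to 11000000 held 66 and 42.

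A few tall shared sites differed in height between the lists. The 588 pairs with at least 20 fragments at both summits were taken, a minimum that leaves out sites tall in 1 list only. The SD of their log2 ratio of XPD to XPB height was 0.34, where counting error alone gave 0.29 (0.26 to 0.32 over 1000 draws). From the median ratio 6 pairs departed by more than 2-fold, where counting error gave 0.54 on average and at most 4. Of these 6, 2 lie close together on chromosome 15 and go opposite ways. The peak from 65587848 to 65589223 had 37 fragments for XPB and 75 for XPD, a log2 ratio of 1.02 (95% counting interval 0.43 to 1.63) relative to the median. The peak from 65596655 to 65598224 had 48 and 23, a log2 ratio of -1.06 (-1.85 to -0.32). The largest departures were on chromosome 1 from 230457820 to 230459411, with 95 for XPB and 38 for XPD (-1.32, -1.90 to -0.76), and on chromosome 17 from 41444800 to 41446326, with 20 and 47 (1.23, 0.45 to 2.07). These intervals cover counting error only and were not adjusted for having been picked as extremes, and with 1 library per antibody, variation between libraries is not separated from a difference between the proteins.

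The first pattern weighed was that most peaks of each list had no partner in the other. A candidate explanation is that they are peaks near the reporting threshold of either list, found in one library and just missed in the other. This requires the strongest peaks to be shared almost without exception, and 100% of the top 1% by score were (lower 95% limits 98.3% for XPB and 97.5% for XPD). These peaks scored at least 811.6 for XPB and 733.2 for XPD, so they cannot show that single-list peaks just missed the threshold. In the highest score decile 80.6% of XPB and 90.3% of XPD peaks were shared, and in the second 48.5 and 61.9%. The result leaves open the 826 XPB and 223 XPD single-list peaks that scored 300 or more. It also leaves open a difference between the proteins or the antibodies, which 1 library each cannot test. Single-list peaks had a peak of the other list within 5 kb of the summit in 18.5% of cases for XPB and 23.8% for XPD, against 16.9% (highest 17.5) and 23.1% (highest 24.3) when the other list was moved locally, although the observed shares exclude overlapping peaks by construction.

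The second pattern was the uneven spread over chromosomes. Extra copies of the dense chromosome 3 windows would raise the read background, and peaks just past the threshold would then need taller summits. At scores of 150 to 170 the mean height there was 1.049 times that of the other autosomes in both lists (intervals 1.02 to 1.08 for XPB and 1.01 to 1.08 for XPD), which argues against a background high enough to raise such summits by 10%; a smaller gain stays open, since how height follows background in the caller was not measured, and gene density was not tested for want of annotation. For chromosome X, a read share of 0.5 of an autosome, with the score falling in proportion, would put its density among the autosomal densities at scores of at least 300: it was 0.863 of the lowest of these for XPB and 0.991 for XPD (0.326 per Mb, interval 0.239 to 0.433, against 0.377 on chromosome 4, and 0.152, 0.0955 to 0.231, against 0.154 on chromosome 18). The autosomal medians at such scores were 0.980 for XPB and 0.595 for XPD, with highest values of 3.02 and 1.78, so chromosome X lay below every autosome and far below the median. Its intervals still include the lowest autosomal density, which leaves a read share of 0.5 neither excluded nor supported as the explanation. The number of X copies itself was not measured. Near-threshold heights on X, 0.96 and 0.92 times the autosomal mean from 11 and 6 peaks, are too few to decide.

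The third pattern was tall summits with low scores, such as the tallest site of both lists on chromosome 1. A background shared by both libraries, as repeats collapsed in the reference could give, would put such summits at the same places in both lists. Of the 216 XPB peaks in the top 1% of height over score, 12.5% (8.40 to 17.7) overlapped an XPD peak in its own top 1%, and 26.4% overlapped any XPD peak. By the rule fixed beforehand (at least 80% for the explanation, under 50% against) this counts against it. The rule was flawed, however: the XPD class holds 146 peaks, so with 1 partner each no more than 67.6% could have matched and the test could not have come out for the explanation, which was noticed only afterwards. That limit spoils only the side for the explanation: a share above 50% was possible, and 12.5% lay well under it. Overlap with any XPD peak has no such limit, and was 26.4% (20.6 to 32.8) against 26.6% of the whole XPB list. The whole list is not a matched reference, because the class is narrower (median width 591 against 833 bp). Overlap also ran from 9.65% in the lowest XPB score decile to 93.4% at 31 or more fragments. This second share therefore decides nothing. The 12.5% argues against the explanation for most of the class, as far as absence from a list can be read. Still, of the 57 class members that overlapped any XPD peak, 27 met one in its own top 1%. That XPD class is only 146 of 14570 peaks, so the explanation stays open for the members with such partners. Of the 15 class members with at least 50 fragments, 11 overlapped an XPD peak in its own top 1% (73.3%, 44.9 to 92.2). For these tallest summits the explanation is left open, and their sequence was not examined.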
